A study of Homo sapiens with 8 samples.

How the data were processed

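RNA of human lung cancer lines was measured by sequencing in 8 libraries, 2 for each combination of a line (A549 or H1299) and a transfection (a control microRNA or miR-29a-3p), per the labels. Total RNA was extracted with TRIzol and made into libraries with a VAHTS RNA-seq kit, per the labels' protocols. The authors deposited 1 table of FPKM values (fragments scaled to transcript length and to the library's mapped total) per gene and library, per the file headers. The submitters' processing notes name StringTie and the genome build GRCh38. Their versions, the aligner, the annotation release, the strand setting and the read length are not given in the sources used here. The table lists 27756 genes for A549 and 28609 for H1299, 31461 in either line and 24904 in both, and no listed gene is at 0 in all 4 libraries of its line. A gene listed for 1 line was taken as 0 in the other, which held for 40 tested genes in the libraries labelled A549 and 80 in those labelled H1299.

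The FPKM values were taken as deposited, with no further scaling between libraries. Genes with at least 1 FPKM in at least 2 of the 8 libraries were tested, which left 14635. The test was limma (version 3.58.1, in R 4.3.3) on log2(FPKM + 1), with a mean for each of the 4 groups and the moderated variance following the mean expression. Fold changes are therefore on the log2(FPKM + 1) scale, which understates the change of low genes. The fit had 4 residual degrees of freedom and a prior of 2.36. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Every adjusted p of a gene is from limma, in this fit unless another is named. The contrasts were miR-29a-3p over control in each line and the difference between these responses (A549 minus H1299). The treatment effect averaged over both lines came from a separate limma fit, with the line as a covariate. That fit has no term for a difference in response, so such a difference counts as spread. Genes that changed by unlike amounts in the lines therefore pass less easily there. The tests were planned for counts or for normalised values, and the normalised form was used because the table holds FPKM.

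The depth of each library was estimated from the table. In FPKM, 1 fragment of a gene has a fixed value set by the gene's exon length and the library's total, and the most frequent such value among genes under 0.2 FPKM gave totals of 12221310 to 15614821 fragments. Between 38.2% and 42.1% of the values from 0.5 to 200 estimated fragments then came out whole within 0.02, so these totals are estimates and no count test was the main result. The labels number the libraries of a group but do not say that they came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The libraries of a group differed by slightly more than sampling noise, with a chi-square per degree of freedom of 1.17 to 1.41 over 769 to 835 genes, and each was kept as its own replicate.

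Gene names and identifiers were those of the file, and 31105 of its 31461 identifiers were found in GENCODE release 29, which gave gene types and positions on GRCh38. The same release gave the 3′ UTR of each gene, taken as the longest of its protein-coding transcripts. Each was searched for the miR-29 seed match as an 8mer, 7mer-m8, 7mer-A1 or 6mer site. The shift of genes with an 8mer or 7mer-m8 site is their median log2 fold change minus that of genes with no 6mer, and it was ranked among those of the 80 7-mers made of the same letters without CG, itself included. Genes without an annotated 3′ UTR were left out of that search.

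Lists of genes were fixed before the data were examined. They were collagens, other matrix and basement membrane proteins, collagen maturation enzymes, matrix proteases and inhibitors, integrins and collagen receptors, reported miR-29 targets outside the matrix, a list that holds FDXR, CCNG1 and CDKN1A and is left without a title here, interferon-stimulated genes, antigen presentation, chemokines and inflammatory mediators, cell cycle genes, epithelial genes, mesenchymal genes, unfolded protein and stress response, cholesterol synthesis, microRNA pathway, immediate early genes, mitochondrially encoded mRNAs and reference genes. Marker lists of A549, H1299, fibroblasts, leukocytes and endothelial cells served as checks of labels and of other cells. Lists with at least 3 tested members were tested with camera from limma at a preset correlation of 0.01, adjusted over the 20 lists within a contrast, and again with an estimated correlation. Each list is given with its members called over all genes tested and with the number adjusted over the list alone.

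The rule for named genes was also fixed before the data were examined. It takes, for each line, the 10 lowest and 10 highest called genes with at least 5 FPKM in a group and no overlap between treated and control libraries, which 33.3% of unchanged genes would show. It adds the 8 lowest and 4 highest protein-coding genes called in both lines that meet these limits in each line, the 3 lowest and 3 highest of the difference between lines, up to 4 members of each list by p, and 25 genes of prior interest. For the difference between lines, genes were limited to protein-coding ones. In at least 1 line these had to reach 5 FPKM in a group and show no overlap. The fixed rule did not state these limits for the difference. Of the members that the lists contribute, the text names a subset chosen after their values were seen, to keep it short. Members of gene families with near-identical copies and genes that overlap others may share fragments, and their values are uncertain.

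The procedures were tested on simulated data with 200 changed genes. In the data, 16% of tested genes were called in the A549-labelled libraries and 50% in the H1299-labelled ones. The simulated spread was set from the replicate pairs of these libraries. The shares below may therefore not carry over to the data, and they cannot cover differences between cultures. The A549 comparison recovered 79% of genes changed 2-fold and 51% of those changed 1.5-fold among 14167 genes, and 6.5% of its 139 calls were unchanged genes. The H1299 comparison recovered 72% and 55% among 14172 genes, with 3.1% of 131 calls unchanged. In a separate simulation, a new draw of 200 genes was raised 2-fold in both lines, with no smaller or downward changes. The averaged fit recovered 91% of them among 14153 genes. A planted seed-site shift of -0.15 in A549 came back as -0.12 and ranked lowest of the 80 7-mers, over 14163 genes.

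Alternatives planned before the data were examined were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, rescaled libraries, no variance trend, each line fitted alone, each library left out in turn, the replicate number as a block, camera with an estimated correlation, other definitions of the 3′ UTR and site, and matrix genes left out of the seed-site comparison. A voom fit of the estimated fragments, the 3′ UTR of the principal transcript and the removal of trends with GC content and 3′ UTR length were added after the data were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 read the table and drew the figures.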

Results

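Gene expression was measured in 8 RNA-seq libraries of lung cancer lines that had been transfected with a control microRNA or with miR-29a-3p, a microRNA known to repress collagen and other matrix genes. The lines were A549, a lung adenocarcinoma line, and H1299, a large cell carcinoma line. Each of the 4 groups held 2 libraries, and the stated purpose was to find potential targets of miR-29a-3p. The libraries held an estimated 12221310 to 15614821 fragments and between 12021 and 12837 genes at 1 FPKM or more. The median difference between replicates was 0.079 to 0.088 on the log2(FPKM + 1) scale.

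The marker genes of the lines lay opposite to the labels. CDKN2A (ENSG00000147889, chromosome 9, 21967753 to 21995301 on GRCh38), a cell cycle inhibitor deleted in A549 and the 1 gene of the H1299 marker list, stood at 24.3 ± 0.72 FPKM (SD, n = 2) in the controls labelled A549 and at 0.082 ± 0.043 (SD, n = 2) in those labelled H1299. ALDH1A1, an aldehyde dehydrogenase abundant in A549, stood at 59.2 ± 2.17 FPKM (SD, n = 2) labelled A549 and 797 ± 17.3 (SD, n = 2) labelled H1299. Of the 8 A549 marker genes, 7 were higher in the H1299-labelled controls. The exception was GPX2, at 1.77 ± 0.86 FPKM (SD, n = 2) labelled A549 and 1.58 ± 0.81 (SD, n = 2) labelled H1299, with overlapping libraries. The CDKN2A level of the H1299-labelled controls did not differ after miR-29a-3p (0.073 ± 0.011 FPKM, adjusted p = 0.90), and that of the A549-labelled ones was 28.1 ± 0.40 (adjusted p = 0.060). Lines are therefore named below as the libraries were labelled, and a direction that depends on the line holds for the label only.

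**Figure D1:**
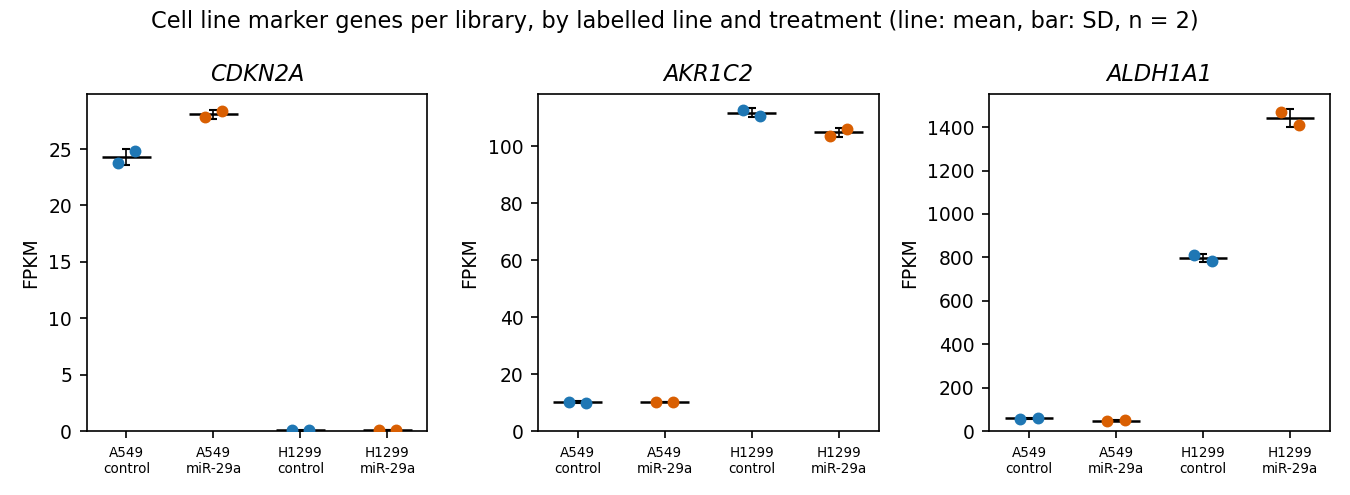
FPKM of CDKN2A, AKR1C2 and ALDH1A1 (y axes from 0) in the 8 libraries, by labelled line and treatment, with points for libraries, lines for means and bars for the SD of 2 libraries. CDKN2A is at or above 23.8 in the libraries labelled A549 and at or below 0.112 in those labelled H1299, while ALDH1A1 averages 59.2 and 797 FPKM in the respective controls.

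In the libraries labelled A549, single genes that build or cross-link matrix, such as LOXL2 and SERPINH1, were lower after miR-29a-3p, and genes of the interferon response were higher. LOXL2 (ENSG00000134013, chromosome 8, 23297189 to 23425328), an enzyme that cross-links collagen, fell from 23.6 ± 0.099 to 6.09 ± 0.24 FPKM (SD, n = 2 each), a log2 fold change of -1.79 ± 0.053 (SE, adjusted p = 4.9e-05). SERPINH1, the collagen chaperone, fell from 19.1 ± 0.22 to 6.57 ± 1.28 FPKM (SD, n = 2 each). MMP14, a membrane-bound protease that degrades collagen, fell from 38.7 ± 0.38 to 12.9 ± 1.06, and NID1, a basement membrane protein, from 9.12 ± 0.34 to 2.71 ± 0.12. CDK6, a kinase that drives entry into the cell cycle, fell from 27.0 ± 1.1 to 9.68 ± 0.72 FPKM, and MYBL2, a transcription factor of dividing cells, from 57.8 ± 0.79 to 20.7 ± 0.41.

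The other genes among the 10 lowest were IER2, TUBA1A, RCC2 and S100A16, with log2 fold changes of -2.41, -1.48, -1.40 and -1.40. IER2 fell from 38.5 ± 0.22 to 6.41 ± 0.52 FPKM (SD, n = 2 each). Its spread was wide in the H1299-labelled libraries (5.20 ± 2.37 and 9.42 ± 8.91 FPKM), and the fit pools the spread of all 4 groups. IER2, an immediate early gene, had an adjusted p of 0.045 and lost its call without any of the 4 A549-labelled libraries (adjusted p = 0.14 to 0.15) or either H1299-labelled control (adjusted p = 0.064), with a pseudocount of 0.1 (adjusted p = 0.060), with no filter on low values (adjusted p = 0.11) and with rescaled libraries (adjusted p = 0.050). TUBA1A belongs to a family of near-identical tubulins, so its value is uncertain. The genes that rose most were SESN2, a stress-induced inhibitor of growth signalling, from 10.4 ± 0.72 to 42.0 ± 0.12 FPKM, and CIPC, a repressor of the circadian clock, from 1.22 ± 0.062 to 6.69 ± 0.46. CHAC1, an enzyme that breaks down glutathione, rose by 1.52 on the log2 scale (adjusted p = 0.00035). The remaining 7 were genes of the interferon response. IFIT3 rose from 159 ± 4.69 to 478 ± 1.25 FPKM and ISG15 from 340 ± 20 to 829 ± 12.0, while IFIT2, IFI44, ZNFX1, DDX58 and USP18 rose by 1.47, 1.38, 1.37, 1.33 and 1.30. Over all 14635 genes tested with limma, 1068 were higher and 1268 lower, of which 41 and 56 changed at least 2-fold. The count of 2336 fell to 1045 to 1196 when any of the 4 A549-labelled libraries was left out and to 1365 when the line was fitted alone.

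The interferon-stimulated list moved furthest upward in the A549-labelled libraries. Of its 34 tested members, 26 rose and 0 fell (28 and 0 adjusted over the list alone), with a median log2 fold change of 0.61 (camera, adjusted p = 3.7e-22). The antiviral gene OASL rose from 57.0 ± 1.51 to 124 ± 3.60 FPKM. Of 27 chemokines and inflammatory mediators, 12 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.31 (camera, adjusted p = 1.7e-05), and CXCL1, which attracts neutrophils, rose from 6.25 ± 0.20 to 11.3 ± 1.33 FPKM. These calls held with an estimated correlation (adjusted p = 0.0065 and 0.047 respectively). IFNB1, the gene of interferon beta, was already at 1.82 ± 0.39 FPKM (SD, n = 2) in the A549-labelled controls and at 7.39 ± 1.15 in the H1299-labelled ones, and no untransfected library was analysed here. After miR-29a-3p it stood at 3.64 ± 0.31 (adjusted p = 0.015) and 8.94 ± 0.081 FPKM (adjusted p = 0.15).

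Reported miR-29 targets outside the matrix fell as a list in the A549-labelled libraries. Of 25 tested members, 1 rose and 14 fell (1 and 18 adjusted over the list alone), with a median of -0.42 (camera, adjusted p = 2.9e-08, and adjusted p = 0.027 with an estimated correlation). TDG, which excises modified cytosine, fell from 1.91 ± 0.070 to 0.764 ± 0.043 FPKM, and TET3, which oxidises methylated cytosine, from 6.16 ± 0.18 to 4.09 ± 0.064. The small GTPase CDC42 fell from 42.6 ± 2.10 to 27.8 ± 1.68 FPKM, and the lactate transporter SLC16A1 from 7.74 ± 0.15 to 5.20 ± 0.18. TET2 fell by 0.42 on the log2 scale (adjusted p = 0.010) and DNMT3B, a DNA methyltransferase, by 0.55 (adjusted p = 0.010). The TET2 call was lost without A549 control 2 (adjusted p = 0.054), and that of DNMT3B without A549 control 2 (adjusted p = 0.050) or miR-29a-3p 2 (adjusted p = 0.054). DNMT3A had a log2 fold change of -0.26 (adjusted p = 0.087), the survival factor MCL1 -0.20 (adjusted p = 0.055) and PIK3R1, a regulator of phosphoinositide kinase, -0.18 (adjusted p = 0.43). TET1 lay under the filter on low values, at 1.05 ± 0.31 FPKM in the controls and 0.495 ± 0.051 after miR-29a-3p.

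Genes of the unfolded protein and stress response rose in the A549-labelled libraries, and cell cycle genes fell. Of 17 stress response genes 9 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.23 (camera, adjusted p = 0.00013, and adjusted p = 0.057 with an estimated correlation). DDIT3, a transcription factor of prolonged stress, rose from 3.78 ± 0.29 to 8.80 ± 0.66 FPKM, and TRIB3, its target, from 8.68 ± 0.28 to 15.9 ± 1.39. Of 34 cell cycle genes, 0 rose and 15 fell (0 and 19 adjusted over the list alone), with a median of -0.25 (camera, adjusted p = 6e-07, and adjusted p = 0.078 with an estimated correlation). RRM2, which makes deoxynucleotides, fell from 16.7 ± 0.79 to 11.8 ± 0.22 FPKM. CDKN1A, a cell cycle inhibitor that is not in this list, fell from 28.1 ± 0.51 to 16.6 ± 0.41.

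Smaller groups passed camera in the A549-labelled libraries and lost the call with an estimated correlation. Of 19 antigen presentation genes, 5 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.20 (camera, adjusted p = 0.0011, and adjusted p = 0.15 with an estimated correlation). HLA-E, a class I molecule of a multigene family whose values are uncertain, rose from 44.2 ± 0.48 to 72.1 ± 1.0 FPKM, while CD274, the gene of PD-L1, stood at 0.566 ± 0.062 and 0.556 ± 0.083 (adjusted p = 0.99). Of 8 immediate early genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.42 (camera, adjusted p = 0.0015, and adjusted p = 0.097 with an estimated correlation), and EGR1 rose from 7.27 ± 0.67 to 17.8 ± 1.23 FPKM. Of 10 epithelial genes, 1 rose and 3 fell (1 and 5 adjusted over the list alone), with a median of -0.28 (camera, adjusted p = 0.018, and adjusted p = 0.14 with an estimated correlation). CLDN1, a tight junction protein, fell from 11.3 ± 0.46 to 4.16 ± 0.18 FPKM. Of 13 mitochondrially encoded mRNAs, 0 rose and 0 fell (0 and 4 adjusted over the list alone), with a median of -0.13 (camera, adjusted p = 0.013, and adjusted p = 0.38 with an estimated correlation). The epithelial call was lost without A549 control 1 (adjusted p = 0.058), with no filter on low values (adjusted p = 0.078) and at a mean of at least 5 FPKM (adjusted p = 0.073), and the mitochondrial one without A549 control 2 (adjusted p = 0.077) or miR-29a-3p 2 (adjusted p = 0.054).

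Other lists did not pass camera in the A549-labelled libraries. Of a list of 29 genes that holds FDXR, CCNG1 and CDKN1A, 7 rose and 5 fell (12 and 6 adjusted over the list alone), with a median of 0.11 and an adjusted p of 0.085. Of 24 matrix proteases and inhibitors, 4 rose and 6 fell (4 and 7 adjusted over the list alone, adjusted p = 0.18). Of 15 integrins and collagen receptors, 1 rose and 4 fell (2 and 4 adjusted over the list alone, adjusted p = 0.20), and of 18 cholesterol synthesis genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone, adjusted p = 0.20). Of 14 mesenchymal genes, 1 rose and 1 fell (1 and 2 adjusted over the list alone, adjusted p = 0.67), and of 13 microRNA pathway genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, adjusted p = 0.67). Of 12 reference genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone, adjusted p = 0.92), with a median of -0.07, a mean of -0.02 and an upward camera statistic. Of the 8 A549 marker genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, adjusted p = 0.58). The mesenchymal median was 0.00, with a mean of -0.02.

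In the libraries labelled H1299, genes of the unfolded protein and stress response were lower after miR-29a-3p, and chemokine and interferon-stimulated genes were higher. KRT80, a keratin, fell from 43.6 ± 0.26 to 2.55 ± 0.58 FPKM (SD, n = 2 each), a log2 fold change of -3.66 ± 0.10 (SE, adjusted p = 9.8e-06). CLDN1 fell from 132 ± 0.53 to 10.9 ± 0.082 FPKM, and COL5A2 (ENSG00000204262, chromosome 2, 189031896 to 189225312), a fibrillar collagen chain, from 55.0 ± 7.03 to 7.52 ± 0.095. TRIB3 fell from 140 ± 6.29 to 15.7 ± 0.33 FPKM, DDIT3 from 20.6 ± 0.84 to 3.09 ± 0.29, and the amino acid transporter SLC7A5 from 524 ± 2.08 to 93.7 ± 1.54.

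STC2, a secreted glycoprotein induced by stress, fell from 165 ± 0.68 to 30.7 ± 0.56 FPKM in the same libraries. BEX2, UAP1L1 and ANKRD1 completed the 10 lowest, with log2 fold changes of -2.47, -2.41 and -2.39. ALDH3A1, an aldehyde dehydrogenase, rose the most among the named genes, from 38.0 ± 1.33 to 594 ± 8.57 FPKM, a log2 fold change of 3.93 ± 0.062 (SE, adjusted p = 2.3e-06). The neutrophil attractants CXCL5 and CXCL1 rose from 208 ± 2.80 to 1134 ± 31.7 and from 77.5 ± 1.42 to 361 ± 10.7 FPKM, though fragments may be shared within their family. The cytokines CSF3 and TNFSF14 rose from 0.804 ± 0.13 to 8.58 ± 0.026 and from 0.489 ± 0.36 to 8.04 ± 0.59 FPKM. HSPA8, a heat shock protein with many pseudogenes, rose by 2.64 on the log2 scale, RRM2 by 2.61, the sulfatase SULF2 by 2.39 and LYNX1 by 2.28. AC092143.1, a gene model that may overlap its neighbours and is uncertain, was listed at 0 in both controls and at 5.21 ± 1.65 FPKM after miR-29a-3p. Over all 14635 genes, 3677 were higher and 3635 lower, of which 457 and 377 changed at least 2-fold. The count of 7312 fell to 3773 when genes were required to average at least 5 FPKM, which left fewer genes to test.

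Chemokine and interferon-stimulated genes rose as lists in the H1299-labelled libraries, as did the list that holds FDXR, CCNG1 and CDKN1A. Of 27 chemokines and inflammatory mediators, 21 rose and 4 fell (22 and 4 adjusted over the list alone), with a median of 0.97 (camera, adjusted p = 1.2e-05), and CCL2, which attracts monocytes, rose from 2.23 ± 0.15 to 12.3 ± 0.61 FPKM. Of 34 interferon-stimulated genes, 27 rose and 1 fell (27 and 2 adjusted over the list alone), with a median of 0.64 (camera, adjusted p = 3.3e-07), and ISG15 rose from 142 ± 8.08 to 224 ± 5.18. Of the 29 members of the latter, 22 rose and 4 fell (22 and 5 adjusted over the list alone), with a median of 0.66 (camera, adjusted p = 8.2e-06). FDXR, a mitochondrial electron carrier, rose from 4.29 ± 0.15 to 16.9 ± 0.16 FPKM, CCNG1 from 4.36 ± 0.17 to 13.8 ± 0.13, and CDKN1A from 92.6 ± 0.83 to 112 ± 2.08. Each of these 3 lists kept its call with an estimated correlation, at an adjusted p of 0.037.

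Genes of the unfolded protein and stress response fell in the H1299-labelled libraries. Of 17 members, 0 rose and 15 fell (1 and 15 adjusted over the list alone), with a median of -0.81 (camera, adjusted p = 3.3e-07, and adjusted p = 0.037 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, fell from 731 ± 7.77 to 277 ± 0.35 FPKM.

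Cell cycle and cholesterol synthesis genes rose in the H1299-labelled libraries, with calls that were lost with an estimated correlation. Of 34 cell cycle genes, 19 rose and 5 fell (21 and 5 adjusted over the list alone), with a median of 0.50 (camera, adjusted p = 5.8e-05, and adjusted p = 0.13 with an estimated correlation). RRM2 rose from 0.739 ± 0.096 to 9.64 ± 0.42 FPKM, PCNA, the replication clamp, from 81.4 ± 7.26 to 340 ± 7.75, and MCM4, part of the replicative helicase, from 1.93 ± 0.014 to 10.3 ± 0.71. Of 18 cholesterol synthesis genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 0.71 (camera, adjusted p = 2.1e-05, and adjusted p = 0.13 with an estimated correlation). The enzymes MSMO1, IDI1 and FDFT1 rose from 4.32 ± 0.17 to 19.3 ± 0.66, from 5.28 ± 0.13 to 14.98 ± 0.050 and from 1.95 ± 0.14 to 4.89 ± 0.045 FPKM.

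Antigen presentation genes, mitochondrially encoded mRNAs and the A549 marker genes also passed camera in the H1299-labelled libraries. Of 19 antigen presentation genes, 12 rose and 3 fell (13 and 3 adjusted over the list alone), with a median of 0.52 (camera, adjusted p = 0.012, and adjusted p = 0.26 with an estimated correlation). HLA-E rose from 37.9 ± 0.43 to 59.9 ± 0.82 FPKM, and CD274 stood at 1.47 ± 0.11 and 1.27 ± 0.88 (adjusted p = 0.58). Of 13 mitochondrially encoded mRNAs, 12 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.35 (camera, adjusted p = 8.9e-05, and adjusted p = 0.26 with an estimated correlation). MT-ND6, which lies opposite other genes and is uncertain without a stated strand setting, rose from 106 ± 13.2 to 238 ± 10.4 FPKM. The mitochondrial share of all estimated fragments was 6.3% in both H1299-labelled controls and 8.2% and 7.9% after miR-29a-3p. Of the 8 A549 marker genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.64 (camera, adjusted p = 0.012, and adjusted p = 0.16 with an estimated correlation). The antigen presentation call was lost at a mean of at least 5 FPKM (adjusted p = 0.057).

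The other lists did not pass camera in the H1299-labelled libraries. Of 25 reported miR-29 targets outside the matrix, 5 rose and 11 fell (6 and 11 adjusted over the list alone, adjusted p = 0.24). CDK6 fell from 14.8 ± 0.56 to 3.24 ± 0.49 FPKM, TET3 from 6.85 ± 0.10 to 3.05 ± 0.00083, TDG from 4.24 ± 0.35 to 1.92 ± 0.0099, CDC42 from 23.1 ± 1.07 to 14.98 ± 0.39 and SLC16A1 from 7.99 ± 0.48 to 4.29 ± 0.048. DNMT3B rose from 0.813 ± 0.028 to 3.81 ± 0.36 FPKM and PIK3R1 from 0.393 ± 0.073 to 1.25 ± 0.19, while DNMT3A (adjusted p = 0.23) and MCL1 (adjusted p = 0.34) did not pass. TET2 fell by 0.23 on the log2 scale (adjusted p = 0.030), a call lost without any 1 of the 4 H1299-labelled libraries (adjusted p = 0.082 to 0.12). TET1, under the filter on low values, was at 0.108 ± 0.053 FPKM in the controls and 0.412 ± 0.036 after miR-29a-3p. Of 24 matrix proteases and inhibitors, 11 rose and 5 fell (11 and 7 adjusted over the list alone, adjusted p = 0.17). Of 15 integrins and collagen receptors, 5 rose and 3 fell (6 and 4 adjusted over the list alone, adjusted p = 0.27). Of 14 mesenchymal genes, 6 rose and 1 fell (6 and 2 adjusted over the list alone, adjusted p = 0.14), and of 10 epithelial genes, 3 rose and 5 fell (3 and 5 adjusted over the list alone, adjusted p = 0.46). Of 13 microRNA pathway genes, 3 rose and 3 fell (3 and 5 adjusted over the list alone, adjusted p = 0.74), with a median of 0.02 and a mean of -0.09. Of 8 immediate early genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone, adjusted p = 0.77), with a median of 0.03 and a mean of -0.04. Of 12 reference genes, 6 rose and 1 fell (7 and 2 adjusted over the list alone, adjusted p = 0.17), and GAPDH rose from 591 ± 17.4 to 840 ± 2.02 FPKM. GAPDH has many pseudogenes, and its value is uncertain.

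**Figure D2:**
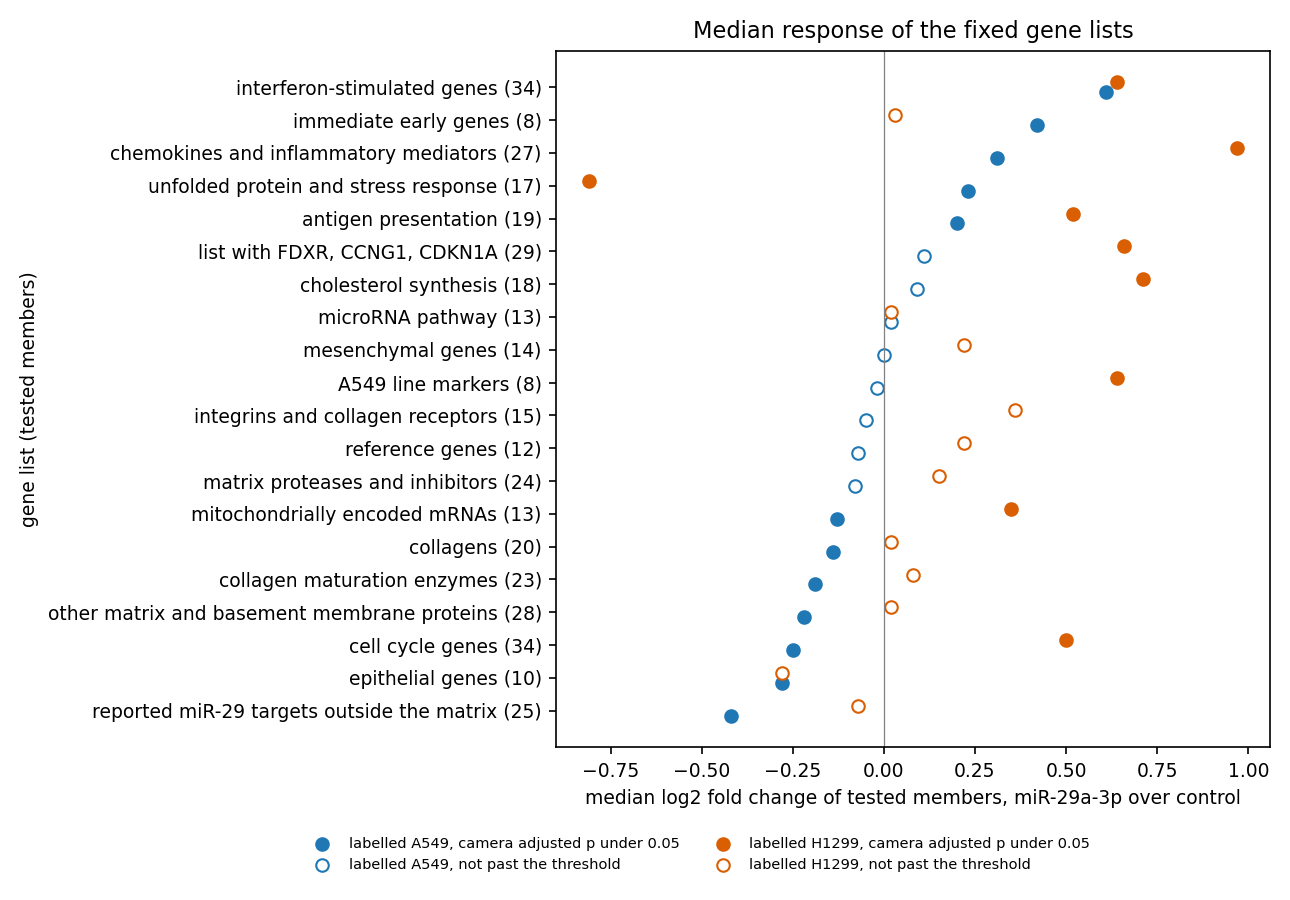
Median log2 fold change (x axis, log2(FPKM + 1) scale) of the tested members of each list (y axis, number of members in brackets) in the libraries labelled A549 and H1299, filled where camera passed at the preset correlation. The interferon-stimulated list lies at 0.61 and 0.64, and the unfolded protein and stress response list at 0.23 and -0.81.

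Collagen genes and their partners were the question raised by the series title, which names collagen degradation. In the A549-labelled libraries, 2 of 20 tested collagens rose and 8 fell (2 and 8 adjusted over the list alone), with a median of -0.14 (camera, adjusted p = 0.0031, and adjusted p = 0.12 with an estimated correlation). That median was -0.03 with no filter on low values, -0.31 with the line fitted alone, -0.33 at a mean of at least 5 FPKM and -0.49 with a pseudocount of 0.1. COL5A2 fell there from 2.25 ± 0.14 to 0.546 ± 0.24 FPKM. The basement membrane chains COL4A1 and COL4A2 fell by 0.29 and 0.35 on the log2 scale (adjusted p = 0.019 and 0.017), from 0.443 ± 0.050 and 0.772 ± 0.058 FPKM, and the fibrillar chain COL5A1 by 0.31 (adjusted p = 0.014) from 0.466 ± 0.0024. These calls were lost for COL4A1 without any A549-labelled library but control 2, for COL4A2 without any but miR-29a-3p 1, and for COL5A1 without any of the 4 (COL4A1 adjusted p = 0.051 to 0.079, COL4A2 0.053 to 0.075, COL5A1 0.053 to 0.062). In the H1299-labelled libraries, 8 collagens rose and 8 fell (8 and 8 adjusted over the list alone), with a median of 0.02, a mean of -0.26 and a downward camera statistic (adjusted p = 0.54). The sign of this median was not stable. It was 0.18 without H1299 control 1, -0.12 without H1299 miR-29a-3p 2 and -0.25 at a mean of at least 5 FPKM. COL4A1 (ENSG00000187498, chromosome 13, 110148963 to 110307233) fell from 33.6 ± 0.23 to 14.0 ± 0.057 FPKM, COL4A2 from 60.5 ± 0.46 to 19.8 ± 0.71, COL12A1 from 4.89 ± 0.054 to 1.92 ± 0.065 and COL5A1 from 15.96 ± 0.23 to 12.2 ± 0.35.

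The collagens best known as miR-29 targets were scarce in these cells. COL1A1, a chain of the main fibrillar collagen, was at 0.244 ± 0.063 FPKM in the A549-labelled controls and 1.26 ± 0.10 in the H1299-labelled ones, with log2 fold changes of -0.17 and 0.14 (adjusted p = 0.18 and 0.15). COL1A2 and COL3A1 were at or below 0.033 FPKM in every group mean and were not tested. COL12A1 did not pass in the A549-labelled libraries (adjusted p = 0.72).

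Other matrix proteins fell as a list in the A549-labelled libraries. Of 28 members, 2 rose and 13 fell (4 and 15 adjusted over the list alone), with a median of -0.22 (camera, adjusted p = 4e-06, and adjusted p = 0.15 with an estimated correlation). FBN1, the main protein of microfibrils, fell from 12.0 ± 0.62 to 4.57 ± 0.0040 FPKM and the laminin chain LAMC1 from 32.2 ± 1.90 to 19.1 ± 0.035, while SPARC, a collagen-binding protein, fell from 1.15 ± 0.071 to 0.286 ± 0.018. Of 23 collagen maturation enzymes, 3 rose and 9 fell (5 and 10 adjusted over the list alone), with a median of -0.19 (camera, adjusted p = 0.022, and adjusted p = 0.18 with an estimated correlation). COLGALT1, which glycosylates collagen, fell from 22.2 ± 0.029 to 10.4 ± 0.35 FPKM, and PLOD1, a lysyl hydroxylase, did not pass (adjusted p = 0.11). The maturation call was lost without A549 control 1 (adjusted p = 0.058), with the line fitted alone (adjusted p = 0.054) and at a mean of at least 5 FPKM (adjusted p = 0.52).

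In the H1299-labelled libraries, matrix genes moved both ways. Of 28 other matrix proteins, 12 rose and 10 fell (12 and 10 adjusted over the list alone), with a median of 0.02, a mean of -0.06 and an adjusted p of 0.95. The matricellular proteins CCN1 and CCN2 fell from 91.5 ± 0.74 to 19.0 ± 0.55 and from 10.9 ± 0.51 to 4.49 ± 0.36 FPKM, FBN1 from 3.14 ± 0.00034 to 1.23 ± 0.046 and LAMC1 from 81.8 ± 1.14 to 49.4 ± 0.48. SPARC was at 0.075 ± 0.068 FPKM in these controls (adjusted p = 0.37). Of 23 maturation enzymes, 9 rose and 5 fell (9 and 5 adjusted over the list alone), with a median of 0.08, a mean of -0.01 and an adjusted p of 0.46. LOXL2 fell from 105 ± 3.43 to 26.3 ± 1.29 FPKM, SERPINH1 from 11.8 ± 1.01 to 4.68 ± 0.97 and COLGALT1 from 17.4 ± 0.59 to 11.6 ± 0.42, while PLOD1 rose from 16.9 ± 0.70 to 32.2 ± 0.46.

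**Figure D3:**
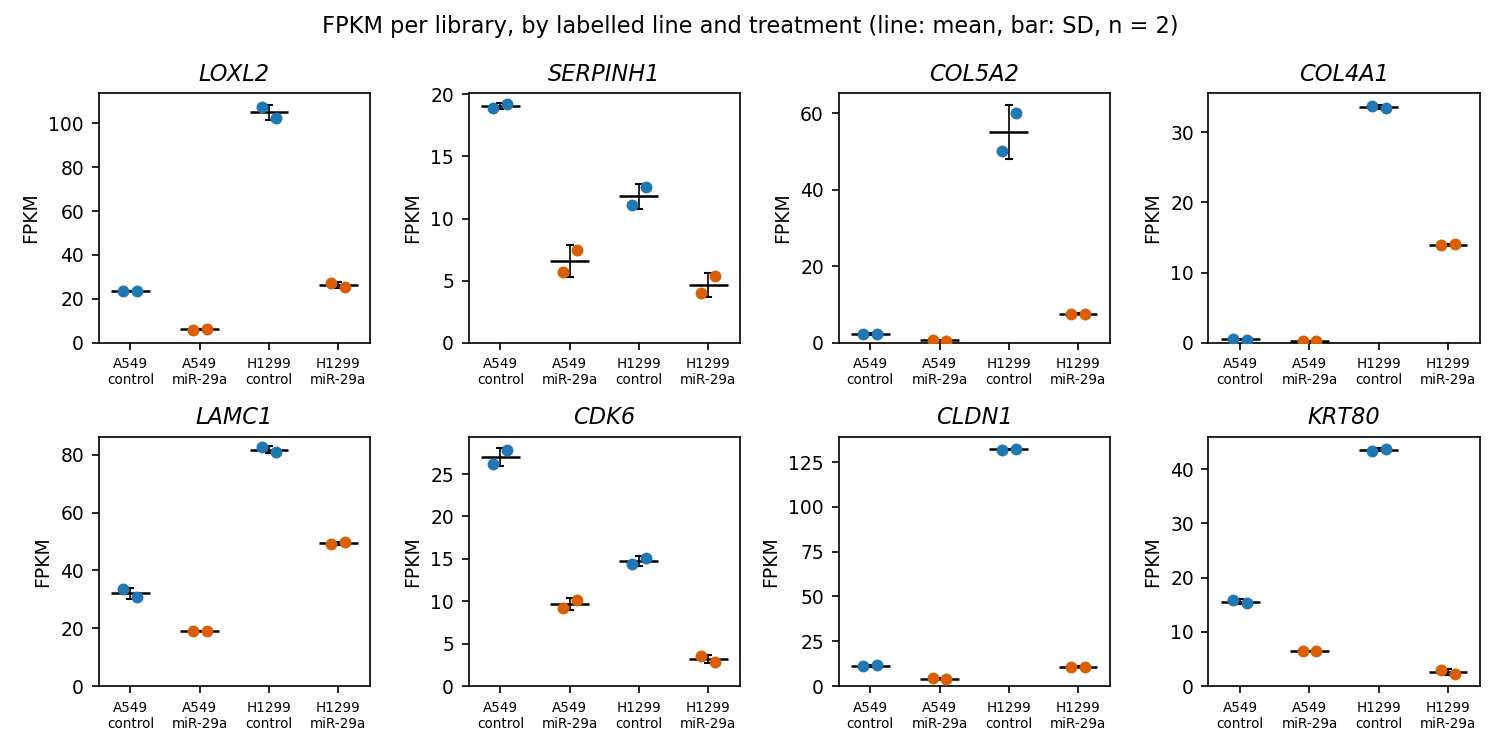
FPKM (y axes from 0) of 8 genes that fell after miR-29a-3p in both lines, by labelled line and treatment, with points for libraries, lines for means and bars for the SD of 2 libraries. LOXL2 falls from 23.6 to 6.09 FPKM in the libraries labelled A549 and from 105 to 26.3 in those labelled H1299, and COL4A1 is near 0 in the former.

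Genes with a miR-29 site in the 3′ UTR fell in both lines relative to genes without one. The 1908 genes with an 8mer or 7mer-m8 site had a median log2 fold change 0.111 below that of the 7660 genes with no 6mer in the A549-labelled libraries (shift -0.111), and 0.157 below it in the H1299-labelled ones (shift -0.157). Both shifts ranked lowest of the 80 7-mers with the same letters, whose second lowest were -0.095 and -0.13. With no filter on low values they were -0.038 and -0.035 and still ranked lowest. In the A549-labelled libraries, 28.9% of the 401 genes with an 8mer fell and 3.7% rose, against 6.2% and 8.7% of genes with no site. In the H1299-labelled libraries, 37.9% of the 8mer genes fell and 19.5% rose, against 22.9% and 30.0%. Of the genes called lower, 408 of 1160 (35.2%) in the A549-labelled libraries and 726 of 3112 (23.3%) in the H1299-labelled ones had an 8mer or 7mer-m8 site, against 16.4% of all 11630 genes with a 3′ UTR. Among those at least 2-fold lower, 32 of 53 (60.4%) and 97 of 308 (31.5%) had a site. TET3 has 10 such sites in its 3′ UTR, COL5A1 and DNMT3A have 4, TDG has 3 and CDK6 has 2. COL4A1 and FBN1 have none in the 3′ UTR searched, though that of their principal transcript holds an 8mer, while CDC42 has 2 in the former and no site in the latter.

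**Figure D4:**
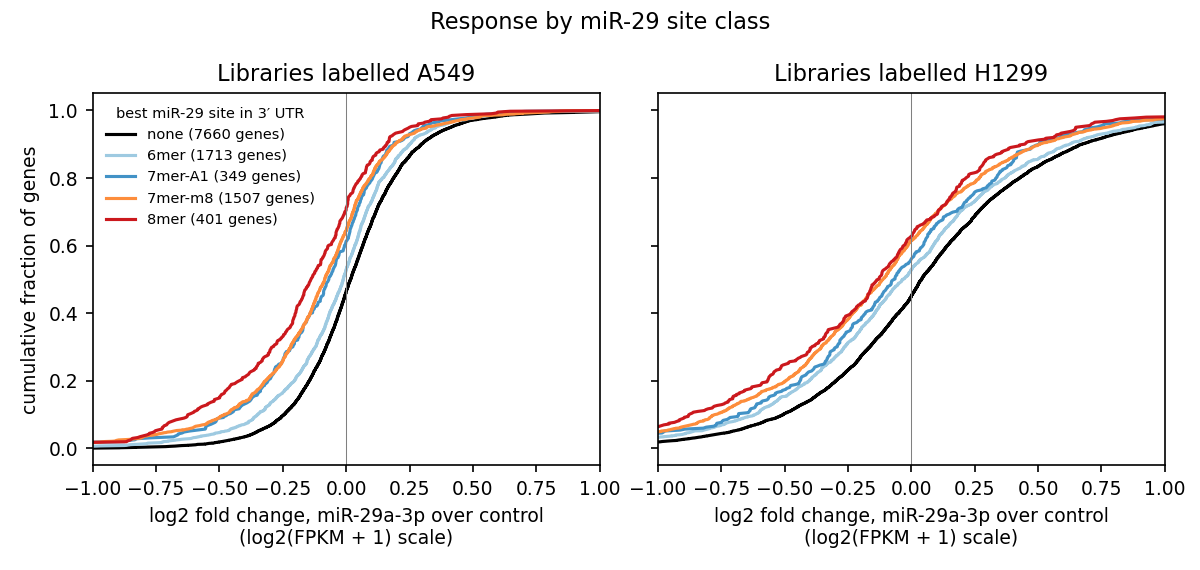
Cumulative fraction of genes (y axis) by log2 fold change after miR-29a-3p (x axis, log2(FPKM + 1) scale, shown from -1 to 1), by the best miR-29 site in the 3′ UTR, in the libraries labelled A549 (left) and H1299 (right). Genes with an 8mer lie furthest to the left, with medians of -0.138 and -0.127, and genes with no site have medians of 0.017 and 0.040.

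Among genes called in both lines that reached 5 FPKM in a group of each, the 8 lowest by the averaged log2 fold change were KRT80, CLDN1, LOXL2, CDK6, RCC2, PMP22, TIMM13 and SERPINH1. Their 3′ UTRs hold an 8mer or 7mer-m8 site, apart from TIMM13 with a 6mer and SERPINH1 with a 7mer-A1 site. RCC2, a regulator of chromosome segregation, fell from 41.9 ± 0.24 to 15.2 ± 0.029 FPKM in the A549-labelled libraries and from 30.7 ± 0.11 to 9.74 ± 0.12 in the H1299-labelled ones. TIMM13, a mitochondrial import chaperone, fell by 1.23 and 1.44 on the log2 scale, and PMP22, a myelin protein, by 1.05 and 1.82. COL5A2 (-1.90) did not reach 5 FPKM labelled A549, nor did CIPC (1.37) labelled H1299. The 4 highest within the same limit were ALDH3A1, CXCL1, MSMO1 and SESN2, with averaged log2 fold changes of 2.12, 1.49, 1.29 and 1.26. Of these, ALDH3A1 did not pass in the averaged fit (adjusted p = 0.082). That fit counts the difference between the lines as spread, and the SE of ALDH3A1 was 0.667 there against 0.062 within each line. The ALDH3A1 call in the A549-labelled libraries (0.31, adjusted p = 0.022) was lost without either A549 control (adjusted p = 0.097 and 0.072) or miR-29a-3p 1 (adjusted p = 0.075).

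Of the 1268 and 3635 genes lower in the libraries labelled A549 and H1299, 596 were shared, against 314.9 for independent lists (Fisher's exact test, one-sided across genes that are not independent, p = 2.6e-72). Of the genes higher, 430 were shared against 268.3 (p = 9.1e-30, the same exact test). The lines share no control libraries. Among the 557 genes lower in both with a 3′ UTR, 238 (42.73%) had an 8mer or 7mer-m8 site against 15.08% of other genes (Fisher's exact test, p = 9.6e-52), and among the 387 higher in both, 27 (6.98%) had one against 16.73% (p = 3.7e-08, the same exact test). Genes called in opposite directions numbered 300 and 251, against 318.6 and 265.3 for independent lists, and the correlation of fold changes across the 14635 genes, which are not independent replicates, was 0.12 (Pearson and Spearman). In the averaged fit, which counts a difference between the lines as spread, 733 genes were higher and 884 lower, against 784 and 755 with rescaled libraries. The count of 1026 shared genes fell to 606 and that of 1617 averaged calls to 85 with the replicate number as a block. The shared genes fell to 528 to 574 without any of the 4 A549-labelled libraries and to 583 with each line fitted alone, and the averaged calls fell to 537 to 576 without any of the 4 H1299-labelled libraries, to 1073, 987 and 956 without A549 control 1, control 2 or miR-29a-3p 1, and to 841 with no filter on low values.

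By the camera p, the stress response differed most between the lines as labelled. Of its 17 genes, 16 were higher in the A549-labelled response than in the H1299-labelled one and 0 lower (16 and 0 adjusted over the list alone), with a median difference of 0.97 (camera, adjusted p = 3.9e-10, and adjusted p = 0.039 with an estimated correlation). Among single genes within the limits for named genes, the largest positive differences were those of TRIB3 (3.87 ± 0.10, SE), DDIT3 (3.44 ± 0.12, SE) and PPP1R15A (3.24 ± 0.059, SE). PPP1R15A, a stress-induced phosphatase regulator, rose from 19.2 ± 0.21 to 38.0 ± 0.38 FPKM labelled A549 and fell from 219 ± 0.26 to 43.9 ± 1.71 labelled H1299. For these genes the H1299-labelled controls stood far above the A549-labelled ones (TRIB3 at 140 against 8.68 FPKM, DDIT3 at 20.6 against 3.78). After miR-29a-3p the levels were closer (TRIB3 at 15.7 against 15.9 FPKM, DDIT3 at 3.09 against 8.80). A state shared by the 2 H1299-labelled controls cannot be told apart from a response to miR-29a-3p. That holds for the stress response, for the cell cycle genes and for other calls that rest on the H1299-labelled libraries alone. Within the same limits, the largest negative differences were those of ALDH3A1 (-3.62), RRM2 (-3.08) and TGOLN2 (-2.99), a protein of the trans-Golgi network. TGOLN2 passed for the difference (adjusted p = 0.035) but within neither line in the joint fit (adjusted p = 0.093 and 0.16), which pools the spread of all 4 groups. It fell from 14.4 ± 0.74 to 3.38 ± 0.45 FPKM labelled A549 but varied from replicate to replicate after miR-29a-3p labelled H1299 (14.4 ± 13.6 FPKM). The call for the difference was lost without any 1 of the A549-labelled libraries or H1299-labelled controls.

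Cell cycle genes differed in the other direction, with 0 of 34 higher and 23 lower (0 and 25 adjusted over the list alone), a median difference of -0.85 and an adjusted p of 4.7e-10 by camera (adjusted p = 0.092 with an estimated correlation). PCNA, for example, differed by -2.36. Of the 29 genes in the list that holds FDXR, CCNG1 and CDKN1A, 6 were higher and 18 lower (6 and 20 adjusted over the list alone), with a median difference of -0.77 and an adjusted p of 0.00019 by camera (adjusted p = 0.092 with an estimated correlation). That median was -0.505 without H1299 control 1. Chemokines, cholesterol synthesis genes, mitochondrially encoded mRNAs and the A549 marker genes were also lower in the A549-labelled response by camera (adjusted p = 0.0076, 3.8e-05, 2.8e-05 and 0.0019). With an estimated correlation these calls were lost (adjusted p = 0.12, 0.14, 0.19 and 0.12 respectively), and that of the chemokines also with a pseudocount of 0.1 (adjusted p = 0.065) and at a mean of at least 5 FPKM (adjusted p = 0.18). Collagens did not differ as a list (median -0.07, mean 0.06, camera adjusted p = 0.94). COL4A1 was at 0.417 of its control FPKM labelled A549 and at 0.416 labelled H1299, so its difference of 0.92 on the log2(FPKM + 1) scale rests on its low level in the former and was 0.33 with a pseudocount of 0.1 (adjusted p = 0.15). That of COL5A1 (0.06, adjusted p = 0.57) was -0.60 and called with a pseudocount of 0.1 (adjusted p = 0.0092), and its FPKM ratios were 0.397 and 0.762. Over all genes, 2650 were higher and 2814 lower in the A549-labelled response. These counts were 2435 and 3135 with rescaled libraries. At a mean of at least 5 FPKM, where fewer genes were tested, they were 1542 and 1442.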

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

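The tests on line labels and on genes silent in the H1299-labelled controls were chosen after the result was seen, as was the removal of GC and 3′ UTR length trends from the seed-site comparison, while the rank of the miR-29 7-mer was planned.

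The stress genes TRIB3, DDIT3 and PPP1R15A rose in one labelled line and fell in the other, and many genes differed in their response between the lines by the interaction test. Over all genes, 5464 differed, and of the 84 named genes tested 67 differed, of which 11 had opposite signs and were called in both lines. That 11 was 7 without A549 control 2 or A549 miR-29a-3p 2, where the calls within a line of NID1, PCNA, HSPA5 and DNMT3B were lost. The differences below are log2 fold changes labelled A549 minus those labelled H1299. Single genes that lay higher in the A549-labelled response were TRIB3 at 3.87, DDIT3 3.44, PPP1R15A 3.24, STC2 3.05, SLC7A5 2.40, CHAC1 1.66, HSPA5 1.57, SESN2 1.30, CIPC 0.84, BEX2 2.78, UAP1L1 2.56, ANKRD1 2.19, KRT80 2.51, CLDN1 2.23, PMP22 0.77, CDK6 0.51, TET3 0.46 and SLC16A1 0.27. Others were COL5A2 at 1.63, COL4A2 1.22, COL4A1 0.92, COL12A1 0.98, CCN1 2.17, CCN2 1.26, IFIT3 0.75, IFI44 0.68, USP18 0.67, ISG15 0.63, DDX58 0.59, IFIT2 0.45, ZNFX1 0.41 and OASL 0.33.

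Single genes that lay lower in the A549-labelled response were RRM2 at -3.08, PCNA -2.36, MYBL2 -2.21, MCM4 -2.11, FDXR -1.82, CCNG1 -1.20 and CDKN1A -1.0. Further genes were TNFSF14 at -2.53, CSF3 -2.23, CXCL5 -2.15, CCL2 -2.08, CXCL1 -1.44, ALDH3A1 -3.62, MSMO1 -1.29, IDI1 -1.24, FDFT1 -0.91, GAPDH -0.35 and MT-ND6 -1.34. Lower too were NID1 at -1.62, MMP14 -1.38, PLOD1 -0.76, SPARC -0.65, COLGALT1 -0.47 and FBN1 -0.33. The others were IER2 at -2.89, TGOLN2 -2.99, HSPA8 -2.53, SULF2 -2.43, LYNX1 -2.18, AC092143.1 -2.06, DNMT3B -1.95, TUBA1A -1.31, PIK3R1 -0.87, S100A16 -0.73 and DNMT3A -0.39.

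Some of these calls were lost on another scale, with the replicate block, with no filter on low values or with 1 library left out. The block ended those of CIPC, TGOLN2, FBN1, SLC16A1 and DNMT3A (adjusted p = 0.054 to 0.087). With no filter, calls were lost for IER2, S100A16, CDK6, CIPC, PMP22, TGOLN2, SLC16A1 and DNMT3A (adjusted p = 0.055 to 0.1). Rescaled libraries ended that of SLC16A1 (adjusted p = 0.056). With a pseudocount of 0.1, calls were lost for COL5A2 (0.94, adjusted p = 0.073), COL4A1 (0.33, adjusted p = 0.15), FBN1 (-0.09, adjusted p = 0.55), SPARC (-1.06, adjusted p = 0.11), IER2 (adjusted p = 0.054) and PMP22 (adjusted p = 0.054). With voom, calls were lost for COL5A2 (adjusted p = 0.11), FBN1 (-0.04, adjusted p = 0.77), SPARC (0.44, adjusted p = 0.75), COL4A1, TNFSF14 (adjusted p = 0.26) and CIPC (adjusted p = 0.051). FBN1 was at 0.381 of its control FPKM labelled A549 and 0.391 labelled H1299. Leaving out 1 library ended the calls of IER2 (-3.29 to -2.49, adjusted p = 0.057 to 0.12), S100A16 (-0.77 to -0.65, adjusted p = 0.059 to 0.082), CDK6 (0.44 to 0.54, adjusted p = 0.050 to 0.074) and CIPC (0.78 to 0.90, adjusted p = 0.061 to 0.086). It also ended those of PMP22 (0.72 to 0.83, adjusted p = 0.054 to 0.078), TGOLN2 (-3.09 to -2.88, adjusted p = 0.078 to 0.092), FBN1 (-0.33 to -0.28, adjusted p = 0.052 to 0.063) and SLC16A1 (0.21 to 0.30, adjusted p = 0.064 to 0.12). The last were DNMT3A (-0.41 to -0.30, adjusted p = 0.081 to 0.12) and PIK3R1 (-0.82 to -0.78, adjusted p = 0.050 to 0.052). In these fits the differences stayed near their values above and the adjusted p moved past the threshold. The difference itself moved by over 1.5 times with 1 library left out, with the call kept, for IER2 without H1299 miR-29a-3p 2 (-1.88, adjusted p = 0.022) and TGOLN2 without H1299 miR-29a-3p 1 (-1.93, adjusted p = 0.002). On other scales it grew for AC092143.1 (-5.12 with a pseudocount of 0.1, -8.02 with voom), PIK3R1 (-1.72 and -1.95 respectively) and DNMT3B (-2.96 with voom), with their calls kept. COL4A2 kept its call at 0.77 with a pseudocount of 0.1 (adjusted p = 0.018) and 0.65 with voom (adjusted p = 0.020).

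Of the gene lists, 10 differed between the lines by camera. Unfolded protein and stress response genes had a median difference of 0.97 and interferon-stimulated genes of 0.26. A549 line markers were at -0.97, cell cycle genes -0.85, the list that holds FDXR, CCNG1 and CDKN1A -0.77, cholesterol synthesis -0.57, chemokines and inflammatory mediators -0.54, mitochondrially encoded mRNAs -0.48, collagen maturation enzymes -0.44, and other matrix and basement membrane proteins -0.36. With an estimated correlation only the stress response kept its call. Without A549 control 1, the calls of the other matrix proteins (adjusted p = 0.050) and the interferon-stimulated genes (adjusted p = 0.050) were lost, and the latter also without A549 miR-29a-3p 1 (adjusted p = 0.056) or H1299 miR-29a-3p 2 (adjusted p = 0.075). The interferon-stimulated call was also lost with the replicate block (adjusted p = 0.061), with rescaled libraries (adjusted p = 0.078) and without the variance trend (adjusted p = 0.051). At a mean of at least 5 FPKM it was lost too (adjusted p = 0.064), as were those of the other matrix proteins (-0.05, adjusted p = 0.56), the collagen maturation enzymes (-0.15, adjusted p = 0.56) and the chemokines (-0.19, adjusted p = 0.18). The chemokines also lost it with a pseudocount of 0.1 (-0.25, adjusted p = 0.065), and their median was -0.20 without H1299 miR-29a-3p 2 and -0.13 with no filter, where the call held.

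CDKN2A and the A549 marker genes lay opposite to the labels of the 2 sets of libraries. Of the 8 A549 markers, 7 were higher in the controls labelled H1299, among them AKR1C2 (112 against 10.1 FPKM), AKR1C3 (70.1 against 7.69) and ALDH1A1 (797 against 59.2), while CDKN2A was higher in all 4 libraries labelled A549. A mixture of both lines in each library is argued against by CDKN2A, whose highest level labelled H1299 was 0.47% of its lowest labelled A549. CDKN2A cannot test for cells without it in the A549-labelled libraries, so a mixture in those alone stays open. An exchange of the line labels may explain these values, and a wrong line in culture under either name stays open and was not tested. The comparison of treated with control libraries within a label does not depend on the name of the line.

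Genes with miR-29 sites fell in both lines, and a 3′ UTR length or base composition that goes with such sites was weighed against the transfected microRNA. The shift of the miR-29 7-mer ranked 1 of 80 in the libraries labelled A549 (next -0.095) and 1 of 80 in those labelled H1299 (next -0.13), so composition shared by these 7-mers does not give it. With trends on GC content and 3′ UTR length removed, the shifts were -0.102 and -0.141. The next 7-mers share 6 letters with the miR-29 site, and the lowest that share no 6mer were at -0.043 and -0.087. An effect of miR-29a-3p through its seed is the biological hypothesis left, found and tested on the same libraries.

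In the H1299-labelled libraries, 435 protein-coding genes were at 0 in both controls and above 0 in both libraries after miR-29a-3p, against 52 the other way round, at a median of 1.4 estimated fragments. The first test, the ratio of estimated totals, gave 1.118, above the bound of 1.1 set for it, so it did not exclude a deeper sequencing of the treated libraries; thinning all 4 to the smallest of their totals, and its bound, were chosen afterwards, and left 364 against 66, a ratio of 5.52. Genomic DNA is argued against by low processed pseudogenes, whose fragments rose 1.103 times against 1.411 for low protein-coding genes. Those of low long intergenic non-coding RNAs lay in between, at 1.228 times. Processed pseudogenes at 0 in both controls and above 0 after miR-29a-3p still numbered 146, against 67 the other way round. A smaller share of genomic DNA is therefore not excluded. Cells of the other line are argued against by the 8 genes abundant there, CDKN2A among them, which stayed at or below 0.61% of the level labelled A549 while the 278 of the 435 silent genes above 0 there stood at a median of 109%, and the rest had no level to compare. The same count labelled A549, not thinned and not tested against this one, was 118 against 84; a wider transcription of low genes after miR-29a-3p may remain, and a difference in the preparation of the libraries stays open, since both treated libraries could share it.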

How the results depend on the processing

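The voom fit, the 3′ UTR of the principal transcript and the removal of GC and 3′ UTR length trends were tests chosen after the result was seen, and the other alternatives were planned.

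Apart from the estimated correlation, calls held in every alternative that gave a value for 44 of 56 named genes in the A549-labelled libraries, 70 of 72 in the H1299-labelled ones and 53 of 67 between the lines, and for 8 of 11, 8 of 9 and 6 of 10 lists besides the collagens. Genes changed in the A549-labelled libraries numbered 1261 with the replicate block, 1365 with each line fitted alone and 1045 to 1968 with 1 library left out. Genes changed in the H1299-labelled libraries numbered 3773, and genes that differed between lines 2984, at a mean of at least 5 FPKM, where fewer genes were tested. Genes changed across both lines numbered 85 with the block, 841 with no filter and 537 to 1152 with 1 library left out. Genes called in the same direction in both lines numbered 606 with the block, 583 with each line fitted alone and 528 to 810 with 1 library left out. Apart from fewer genes or libraries, the cause was not tested. The block took residual degrees of freedom, and replicate numbers do not pair the libraries (correlations of -0.037 to 0.063).

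With an estimated correlation, which cannot move the median of -0.136, the collagen list in the A549-labelled libraries lost its call (adjusted p = 0.12), and the calls of gene lists within a line numbered 7. The call held in the other alternatives, at a median of -0.034 with no filter, -0.309 with the line alone, -0.328 at a mean of at least 5 FPKM and -0.486 with a pseudocount of 0.1. Between the lines, COL4A1 was at -0.002 with voom, and COL5A1 at -0.60 with a pseudocount of 0.1 (adjusted p = 0.0092) and -0.92 with voom (adjusted p = 0.0063), since both are low labelled A549 and the main scale understates their change. SPARC was at 0.44 with voom and -1.06 with a pseudocount of 0.1, and the cause was not tested. The miR-29 seed-site shifts were -0.038 and -0.035 with no filter.

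Rescaling the libraries moved the median log2 fold change of all genes from 0.001 to 0.008 labelled A549 and to 0.038 labelled H1299, where 4216 genes were then higher and 3315 lower, and it left 784 higher and 755 lower across both lines. A library left out leaves an arm with 1, assumed to vary like the others. Alternatives planned for counts (TMM, DESeq2) were not run, as the table holds FPKM.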

Other observations

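The looks at single microRNAs, at CDKN2B and MTAP and at splits within the lines were tests chosen after the result was seen, and the other tests here were planned.

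Marker genes of other cell types were low apart from CD68. The highest group mean of a fibroblast marker was 1.66 FPKM (LUM), that of an endothelial marker 0.29 (KDR) and that of a leukocyte marker 24.2 (CD68), with CD14 at up to 0.958. After miR-29a-3p in the H1299-labelled libraries, CD68 rose from 8.11 ± 0.033 to 24.2 ± 1.0 FPKM (SD, n = 2 each, adjusted p = 2.1e-05) and LUM from 0.878 ± 0.014 to 1.66 ± 0.015 (adjusted p = 0.001). CD68 is a lysosomal gene that many cancer lines express. CDKN2B and MTAP, which neighbour CDKN2A and were chosen after their values were seen, stood at 5.58 and 1.41 FPKM in the controls labelled A549 and at 0.047 and 0.42 in those labelled H1299.

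Targets of other microRNAs could rise if the transfected miR-29a-3p displaced these from the silencing complex. Genes with a let-7, miR-17, miR-21 or miR-30 site and no miR-29 site lay 0.009 (A549-labelled) and 0.012 (H1299-labelled) above genes with none of these sites, below the 95th percentiles of permuted 7-mers of 0.018 and 0.023. These permuted 7-mers hold the letters of the miR-29 site and were each taken singly. Their 95th percentile is therefore not matched to the base composition of the other sites, nor to a set of several sites. As 1 set the genes did not rise beyond that level, which cannot decide whether displacement took place. Looked at singly, genes with a let-7 site (0.022 and 0.036), a miR-17 site in the A549-labelled libraries (0.019) and a miR-21 site in the H1299-labelled ones (0.028) lay above it.

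The list that holds FDXR, CCNG1 and CDKN1A missed the threshold in the libraries labelled A549 (adjusted p = 0.085). It passed there without either H1299-labelled control (adjusted p = 0.047), with a pseudocount of 0.1 (adjusted p = 0.044) and with no filter on low values (adjusted p = 0.047). In the libraries labelled H1299, 22 of 29 members rose.

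The count of genes changed across both lines, such as LOXL2 and CDK6, was compared with other splits of the 8 libraries. Of 34 splits into 4 and 4, with the line as a covariate, 1 gave as many genes, the real split with 1617. The highest of the others had 176, the split with treatment reversed in 1 line. The other splits were fitted without a term for the real treatment, so its effect stays in their spread and lowers their counts. Their counts therefore do not show how many genes would be called without an effect of treatment. A share under 5% of all splits had been set as the bound, but splits that take 3 libraries from 1 line and 1 from the other do not follow the design. Of the 18 that take 2 from each line, 1 gave as many genes, the real split, and 18 are too few for a share under 5%. The split equal to the lines could not be fitted. With the replicate number as a block the count was 85.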
